A study of Mus musculus with 4 samples.

How the data were processed

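Single-cell RNA libraries were made from 4 sorted cell samples of MMTV-neu mice, in which the mouse mammary tumor virus promoter drives a rat Erbb2 (HER2, neu) transgene in the mammary epithelium. Per the labels, the strain was FvB. The early stage was 14 to 18 weeks of age with no palpable tumor, and the late stage was over 20 weeks. At each stage 1 library came from the lungs and 1 from the primary site, which was the mammary gland at the early stage (early lesion) and the primary tumor at the late stage. Per the labels' protocols, the tissue was dissected and digested, and CD45- HER2+ cells were sorted and encapsulated with the 10x Chromium 3' v2 kit, then sequenced on an Illumina NextSeq 550. The sources used here do not give whether a library came from 1 mouse or from several.

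The files deposited by the authors hold counts: whole-number UMI counts (a UMI is a tag on 1 captured RNA molecule) per gene and barcode, with no normalization and with all 737280 barcodes of the kit listed in each library. The genome build was mm10 per the submitters' processing notes. The aligner, the counting software and the annotation release were not given in the sources used here. Gene positions were taken from GENCODE mouse release M21, 1-based on mm10, for genes whose identifier matched. The files carry no separate feature for the rat transgene, so the Erbb2 counts do not separate the rat from the mouse gene.

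Cells, classes, gene lists, named genes and comparisons were defined before the data were examined, and exceptions are named where they occur. A barcode was called a cell with at least 500 UMIs and at least 1/10 of the 99th percentile of the 3000 highest totals of its library, at least 250 detected genes and at most 20% of UMIs from mitochondrial genes. The resulting UMI minimum was 500 in both lung libraries, 911 in the early lesion and 534 in the primary tumor. Doublets were kept in the main values and removed in an alternative. Cells of all libraries were clustered together without batch integration: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0. Each of the 14 clusters was named from 20 marker lists of cell types fixed beforehand, which cover mammary luminal and basal cells, lung epithelial, mesothelial, endothelial, lymphatic endothelial, stromal, adipocyte, Schwann and blood cell types. The names were rebuilt here, carry the ending "-like" and may differ from the study's own.

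For each comparison, counts were summed over the called cells of a library and scaled to the total of the sum as CPM, the customary unit for such sums. Ratios are log2 ratios of CPM after adding 0.5 counts to each sum. With 1 library per group no comparison allowed a test, a standard error or a check between replicates, and a model of site and stage over the 4 libraries together was not fitted. Ratios carry exact 95% intervals from the Poisson counts of both sums, and shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. A share of 0 is given with the share that 3 counts would make. Both kinds of interval cover counting error only, not the spread between mice. The ratio intervals treat each UMI as an independent draw, so they also leave out the spread between cells. They are too narrow where a few cells hold most counts of a gene. A gene was called higher or lower when its ratio was at least 2-fold and its interval excluded a ratio of 1. Where 1 sum held 0 counts, the fold is given as a lower bound against a floor of 3 counts in that sum, with the count of the other sum taken as exact. No fold is given where both sums held 3 counts or fewer.

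The 20 fixed gene lists were epithelial, mesenchymal, pluripotency and early embryo, dormancy, cell cycle, milk and alveolar, hormone-sensing luminal, basal and myoepithelial, ERBB signalling, Wnt, TGF-beta and BMP, extracellular matrix, interferon, MHC class I, MHC class II, hypoxia and glycolysis, oxidative phosphorylation, dissociation stress, unfolded protein response, and inflammation and NF-kB. Members with at least 20 counts over both libraries were used. Each list is summarised by the median log2 ratio of its members and by its percentile among 10000 random lists of the same size matched on mean expression, given as a description of these libraries and not as a test.

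Named genes were chosen by rule: among genes at 50 CPM or more in either library, the 10 highest and 10 lowest by the interval bound nearest to a ratio of 1. Mitochondrial, ribosomal protein, predicted (Gm), clone (Rik) and pseudogene entries were left out. The rule added up to 4 members of each list by the same bound, and Erbb2, Ptprc (CD45), Zfp281, Cdh11 and Nr2f1 in every comparison. Shares of cells with at least 1 UMI of a gene were computed after thinning each cell to 1000 UMIs, with shallower cells left out, and without thinning. Free RNA was estimated from barcodes with 1 to 50 UMIs.

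The workflow was tested on simulated data with known fold changes for each comparison, drawn as Poisson counts without spread between cells. For early lung over early lesion (13794 genes) the 95% intervals held the true ratio for 97.7% of genes, and genes set to change 2-fold, 4-fold and 8-fold were called in 52.2%, 100% and 100% of cases. For late lung over primary tumor (14377 genes) coverage was 97.7% and the calls were 52.2%, 100% and 100%. For late over early lung (12423 genes) coverage was 98.1% and the calls were 47.8%, 92.5% and 100%. For primary tumor over early lesion (14342 genes) coverage was 96.9% and the calls were 58.2%, 100% and 100%. Among genes set not to change, 0.908%, 0.105%, 1.46% and 0% were called in the same order of comparisons, and 8%, 3%, 3% and 4% of unchanged lists fell outside the 95% range of random lists. All 20 changed lists were found in each comparison, and 200 of 200 simulated cells of each library received the right class.

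The alternatives were a UMI minimum of 500 or of 1000 in every library, a mitochondrial share of at most 10%, removal of the highest doublet scores, Leiden resolution 0.5 or 2.0, median-of-ratios scaling, a mean over cells in place of a sum, list members with at least 100 counts or at least 1 count, 5 added counts, removal of immune-like, erythroid-like or platelet-like clusters, subtraction of 5% free RNA, and thinning to 2000 UMIs. Sums without cells over 10000 UMIs were added after the data were seen. Computation used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9. Raw reads were not analysed here.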

Results

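The data are 4 droplet single-cell RNA libraries of sorted CD45- HER2+ cells from MMTV-neu mice, 1 library for each combination of site (lung, primary site) and stage (early, late). With 1 library per group, the intervals given are exact 95% intervals for counting error only. The labels call the lung cells disseminated cancer cells. The libraries held 743765 UMIs in the early lung, 1070236 in the late lung, 6366768 in the early lesion and 3403140 in the primary tumor. Called cells numbered 185 in the early lung, 210 in the late lung, 1085 in the early lesion and 425 in the primary tumor. Their median depth was 772, 811, 2865 and 1673 UMIs, in the same order, and the median number of detected genes was 431, 461.5, 1074 and 804. Mitochondrial RNA made up a median 3.46% and 2.71% of the UMIs of a lung cell, against 0.119% in the early lesion and 0.463% in the primary tumor. A few cells over 10000 UMIs held much of some sums: 8 cells held 42.2% of the UMIs of the late lung cells and 18 held 54.7% in the tumor, against 1 cell with 5.60% in the early lung and 21 with 6.77% in the early lesion.

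The lung libraries consisted mainly of cells with lung expression profiles. In the early lung, 76 of 185 cells (41.1%, 95% interval 33.9% to 48.5%) were endothelial-like, with Cldn5, Ramp2 and Egfl7 among the leading genes of their cluster. A further 61 (33.0%, 26.3% to 40.3%) were like alveolar type 1 cells, led by Ager, Cldn18 and Hopx. Another 23 were pericyte or smooth muscle-like, 13 airway secretory-like (Scgb1a1, Scgb3a2) and 12 fibroblast-like (Dcn, Mfap4, Col3a1). The leading genes of the airway secretory-like cluster also included the alveolar type 2 markers Sftpc, Sftpa1, Sftpb and Cxcl15. The late lung held 92 of 210 alveolar type 1-like cells (43.8%, 37.0% to 50.8%), 59 endothelial-like (28.1%, 22.1% to 34.7%), 26 pericyte or smooth muscle-like, 19 airway secretory-like and 6 fibroblast-like cells. The 6 late endothelial-like cells over 10000 UMIs held the fixed fibroblast markers at 2237 CPM, against 63.1 CPM in the other 53. No cell of either lung library was left without a class.

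Mammary luminal-like cells made up 1057 of 1085 cells of the early lesion (97.4%, 96.3% to 98.3%) and 338 of 425 cells of the primary tumor (79.5%, 75.4% to 83.3%). They were 0 of 185 cells in the early lung, where the exact interval reaches 1.97% and 3 cells would make 1.62%. In the late lung they were 8 of 210 (3.81%, 1.66% to 7.37%). In the early lung they were 3 cells at Leiden resolution 2.0 and 3 of 174 with mitochondrial shares of at most 10%. These are shares of cells that passed the CD45- HER2+ sort. Of the 8 late lung cells, 5 held between 6 and 389 UMIs of milk protein genes, foremost Wfdc18 and Csn3, where the free RNA would give 1.91 to 8.07 at their depth, and 3 of the 5 held over 10 times that. Of the others, 1 held 2504 Hbb-bs UMIs (beta globin), 1 held 243 UMIs of Mbp, the myelin basic protein gene, and 1 held 501 UMIs in total. With a UMI minimum of 1000 the luminal-like share was 14.5% of the 55 early and 24.1% of the 79 late lung cells. There a cluster of 8 early lung, 13 late lung and 42 lesion cells, led by the stromal genes Gsn, Tpm2, Postn and Bgn, took the luminal-like name. Early lesion luminal-like cells lay mainly in clusters led by milk genes (279 and 291 cells), by cell cycle genes (288), by immediate early genes such as Fos and Atf3 (137) and by Hp and Spp1 (59). Tumor luminal-like cells lay mainly in 2 clusters with few cells of other libraries, which held 287 and 49 of them, the smaller led by cell cycle genes such as Tk1 and Prc1. Clusters taken almost wholly from 1 library may stand for that library. The unnamed share was 20.2% (16.5% to 24.4%) in the tumor and 0.922% in the early lesion. It was 4.23% in the tumor with mitochondrial shares of at most 10% and 6.82% in the lesion at Leiden resolution 2.0. In the tumor it comprised 20 cells with Nf1, Auts2 and Aqp5 among their leading genes, 17 of them over 10000 UMIs (median 40244.5), and 66 shallow cells led by Car6, Aqp5 and mitochondrial genes, with a median of 907.5 UMIs and 11.99% mitochondrial RNA.

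**Figure D1:**
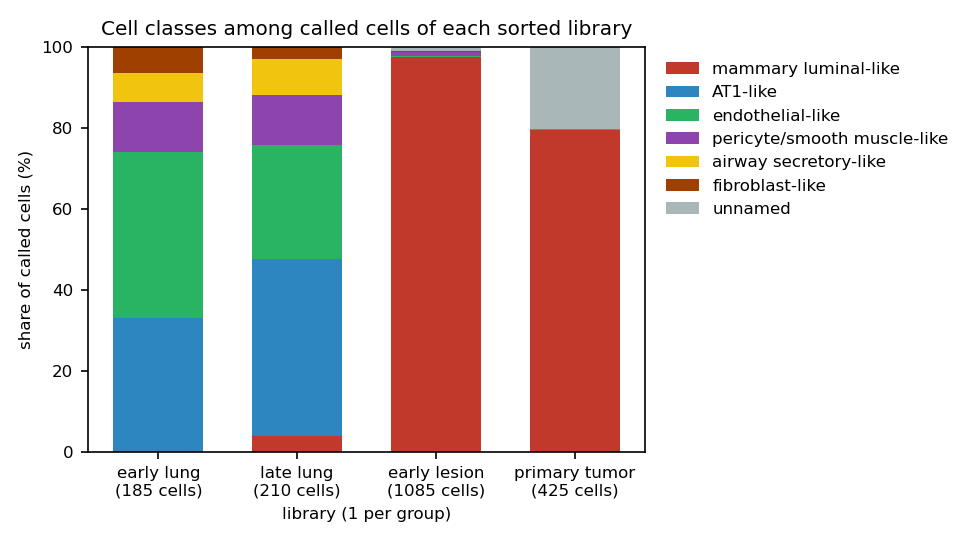
Stacked bars of the share of called cells in each rebuilt class (percent) for the 4 libraries. Luminal-like cells fill 97.4% of the early lesion and 79.5% of the primary tumor, while lung classes fill the lung libraries except for 3.81% luminal-like cells in the late lung.

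Epcam, an epithelial adhesion gene, was found in 561 of 1041 early lesion cells thinned to 1000 UMIs (53.9%) and in 104 of 312 primary tumor cells (33.3%). It was found in 5 of 55 early lung cells (9.09%) and 8 of 79 late lung cells (10.1%). Thinning left out 44 lesion, 113 tumor, 130 early lung and 131 late lung cells, and the shares without thinning were 82.1%, 47.1%, 5.41% and 8.10%. Vim, the intermediate filament of mesenchymal and endothelial cells, was found in 32.7% of early and 22.8% of late lung cells, against 1.54% in the lesion and 0.641% in the tumor. Sftpc, a surfactant gene that mammary cells should lack, was found in 10.9% and 12.7% of the lung cells and in 0 of 1041 lesion and 0 of 312 tumor cells. Top2a, a gene of dividing cells, was found in 47 of 1041 lesion cells (4.51%) and 5 of 312 tumor cells (1.60%), and in none of the thinned lung cells. Mki67 was found in 2.31% of the lesion cells and 2.56% of the tumor cells. These shares include any free RNA, which held Sftpc at 1125 and 1208 CPM in the early and late lung, 4.68 in the lesion and 1.36 in the tumor. In the same order it held Vim at 731, 769, 43.3 and 5.45 CPM and Epcam at 107, 62.7, 834 and 926 CPM.

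Erbb2 (chromosome 11, 98412470 to 98437716, plus strand) had few UMIs everywhere. It was found without thinning in 2 of 185 early lung, 2 of 210 late lung, 28 of 1085 lesion (2.58%) and 29 of 425 tumor cells (6.82%), and after thinning in 0, 1, 5 and 8 cells. Ptprc (CD45, chromosome 1, 138062861 to 138175708, minus strand), the marker sorted against, was found in 2 of 1085 lesion cells and in none of the other libraries. Nr2f1 (chromosome 13, 78188973 to 78199757, minus strand), a nuclear receptor gene known from studies of dormant cancer cells, was found without thinning in 4 of 185 early lung (2.16%) and 4 of 210 late lung cells (1.90%), and in 0 of 1085 lesion and 0 of 425 tumor cells. Zfp281 (chromosome 1, 136624901 to 136630053, plus strand), a transcription factor gene of early embryonic cells, was found in 0, 3, 18 and 11 cells of the early lung, late lung, lesion and tumor. Cdh11 (chromosome 8, 102632095 to 102785642, minus strand), a mesenchymal cadherin gene, was found in 2, 7, 20 and 8 cells. The lung cells were shallower than the lesion and tumor cells, so these unthinned shares compare unequal depths. The free RNA of the early lung, late lung, lesion and tumor held Erbb2 at 17.1, 3.14, 10.5 and 34.04 CPM, where the summed cells held 14.7, 7.28, 7.43 and 47.8 CPM. It held Zfp281 at 21.4, 3.14, 8.18 and 5.45 CPM and Cdh11 at 8.55, 15.7, 5.26 and 2.72 CPM, and Nr2f1 at 25.7 CPM in the early lung.

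**Figure D2:**
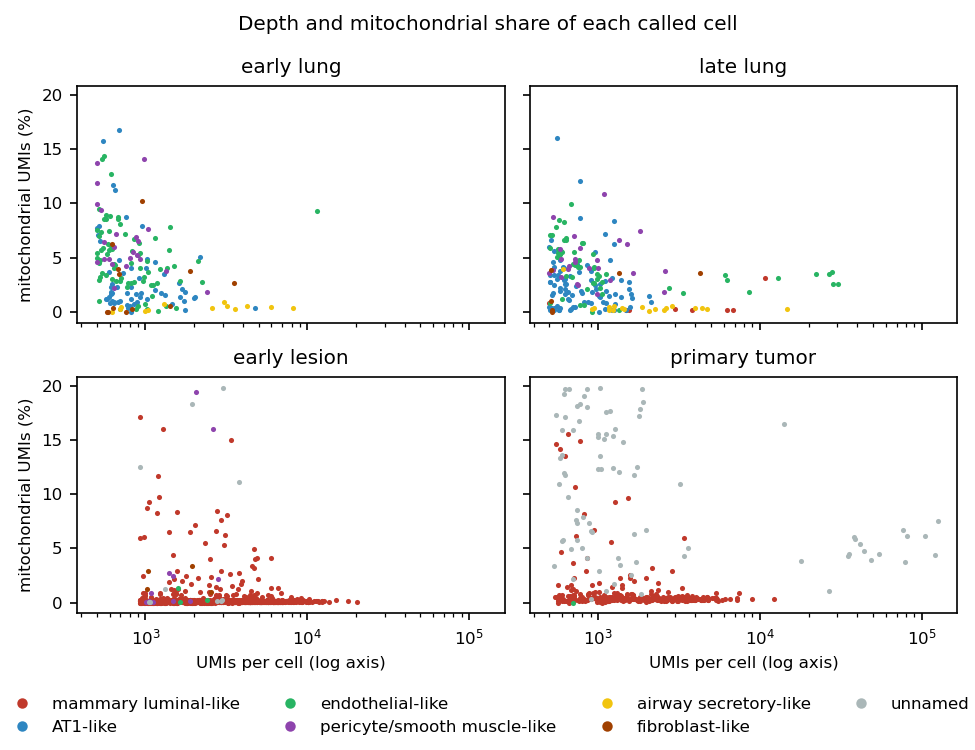
UMIs per called cell (log axis) against mitochondrial percent in 4 panels, 1 per library, with each point a cell coloured by class. Most early lesion cells lie under 1% mitochondrial RNA (median 0.119%), and the tumor panel holds deep unnamed cells up to 125434 UMIs.

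The comparison of early lung with early lesion asks how cells sorted from the lung before a palpable tumor differed from cells of the mammary gland at the same stage. Neither lung library held the 30 luminal-like cells set as the minimum for a comparison within that class. The ratios between sites therefore set mainly lung cell classes against mammary cells. They cannot show how mammary-type cells in the lung differed, for dormancy, cell cycle or any other list. Among the genes named by rule, lung genes such as Scgb1a1 and Ager were far higher in the lung library. Of 18 measured milk and alveolar genes, 17 were lower there. Scgb1a1 (chromosome 19, 9083636 to 9087958, minus strand), the secretory protein of airway club cells, had 22815 counts in the early lung and 21 in the lesion (log2 ratio 14.26, interval 13.68 to 14.99). Ager (chromosome 17, 34597862 to 34600936, plus strand), a marker of alveolar type 1 cells, had 1134 against 2 counts (13.04, 11.50 to 16.40). Csn2 (chromosome 5, 87692624 to 87699630, minus strand), the beta-casein gene, had 9 counts in the lung against 199793 in the lesion (-10.15, -11.36 to -9.30). The alpha-casein genes Csn1s1 (2 against 64657 counts, -10.45) and Csn1s2a (15 against 212196, -9.53) showed the same side.

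Among the other genes with the largest differences, the alveolar genes Hopx (9.69, 9.08 to 10.44) and Cldn18 (296 against 1 count, 11.84) and the airway gene Scgb3a2 (11.46) were higher in the early lung. Sec14l3 was at least 1040-fold and Inmt, a lung stromal gene, at least 783-fold higher, with 0 counts in the lesion. On the lesion side stood Wfdc18, a whey acidic protein family gene (-8.26), Glycam1, a milk mucin gene (-7.79), and Trf, the transferrin gene (-7.11). Thrsp, a regulator of milk lipid synthesis, was at least 86.5-fold and Lalba, the alpha-lactalbumin gene, at least 60.7-fold lower in the lung. The median log2 ratio of all 555 genes compared for scaling was 0.38, against which the other ratios can be read.

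Milk and alveolar genes were lower in 17 of 18 measured members, with a list median of -6.87, below all 10000 matched random lists, and of -5.60 with genes at 0 counts set to their bound. Cell cycle genes were lower in 25 of 31 members and higher in none (median -3.59, and -1.93 at the bounds, weaker still with 5 added counts). Ube2c was at least 22.4-fold and Birc5 at least 11.7-fold lower, and Hmgb2 stood at -3.77 (-4.78 to -3.02). Epithelial genes were lower in 11 of 20 members, including Epcam (15 against 3366 counts, -3.55, -4.44 to -2.88), the tight junction gene Cldn3 (-4.47) and Cd24a (-3.08), and higher in 2, including the keratin gene Krt7 (5.61, 5.21 to 6.05). Their median was -2.16 and -1.12 at the bounds, with 5 added counts -0.92.

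Genes of supporting tissue stood higher in the early lung. Extracellular matrix genes were higher in 10 and lower in 1 of 11 members (median 5.48, above all random lists), among them Col4a2 (7.09), Bgn (6.33) and Postn (5.81). Mesenchymal genes were higher in 5 of 6 members (median 5.49, percentile 99.98), including Vim (5.50), Sparc (5.48) and the pericyte receptor gene Pdgfrb (5.95). In the TGF-beta and BMP list 7 of 11 members were higher and 2 lower (3.02, percentile 99.95), with the BMP target genes Id1 (7.42) and Id3 (6.87) highest. MHC class II genes were higher in 3 of 4 members (3.63, percentile 99.2), among them Cd74 (4.36). Of the MHC class I list 3 of 11 members were higher and 1 lower (-0.22, percentile 38.5), with H2-D1 at 1.31. The interferon list had 3 of 10 members higher (0.39, percentile 56.7), foremost Ifitm3 (5.24).

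Dormancy genes were higher in 8 and lower in 2 of 15 members (median 1.84, percentile 99.65, and 0.07 on the 6 members with at least 100 counts). Cdkn1a, the p21 inhibitor of the cell cycle, stood at 7.08 (5.95 to 8.70), Nr2f2 at 6.11 and Cdkn1c at 4.82, while Igfbp5 was lower (-4.07). Nr2f1 had 6 counts against 0, or 29.5 CPM, close to the 25.7 CPM of the free RNA of the early lung. The pluripotency and early embryo list had 4 members higher, 1 lower and 3 neither (median 1.10, percentile 98.4, and 1.72 at the bounds). Its higher members were led by the Krüppel-like factors Klf2 (4.43) and Klf4 (3.36) and by Tbx3 (4.97), and Myc was at least 4.43-fold lower. With members of at least 100 counts alone its median turned to -0.15. Zfp281 had 0 counts against 20 and Cdh11 2 against 20 (1.17, -2.25 to 2.93), and neither difference was detectable at this depth. Erbb2 had 3 against 28 counts (1.18, -1.37 to 2.68).

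ERBB signalling had 3 members higher and 1 lower of 8 (0.76), with the ligand gene Hbegf at 7.17 and Phlda1 at -1.94. The hormone-sensing list, which also holds the alveolar type 2 marker Cxcl15, had 2 of 3 members higher (4.51, percentile 98.9, Ly6a 6.23). The Wnt list had 1 higher (Nkd1, 6.48), 1 lower (Wnt5b, at least 3.42-fold) and 1 neither (1.27). Basal and myoepithelial genes were higher in 3 and lower in 2 of 9 members (-1.15, and 1.29 at the bounds), with Krt14 at least 17.2-fold lower. Hypoxia and glycolysis genes were lower in 7 and higher in 3 of 16 members (-0.75, and -0.25 at the bounds), with Eno1 at -2.42 and Vegfa, a growth factor gene of blood vessels, at 4.58. Dissociation stress genes were lower in 8 and higher in 2 of 20 (-0.55), with Fos at -2.88 and Dusp1 at 3.23. Inflammation and NF-kB genes had 3 members lower and 2 higher of 11 (-1.72, and 0.02 at the bounds), with Lcn2 at -5.51 and Icam1 at 3.95. Oxidative phosphorylation genes were lower in 3 of 23 (-0.30, Atp5b -1.53), and unfolded protein genes were higher in 3 and lower in 2 of 16 (-0.20), with Xbp1 at -2.37.

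The comparison of late lung with primary tumor asks the same question of site in mice with tumors. With 8 luminal-like cells in the late lung, its ratios again set mainly lung cell classes against mammary cells. The lung genes Scgb1a1 and Ager and the endothelial gene Cldn5, named by rule, were higher in the lung library. Of 14 measured milk and alveolar genes, 11 were again lower. Scgb1a1 had 33957 counts in the late lung against 13 in the tumor (13.44, 12.72 to 14.40) and Ager 1518 against 3 (10.91, 9.58 to 13.41). Cldn5 (chromosome 16, 18776847 to 18778262, plus strand), a tight junction gene of blood vessels, had 663 against 0 counts, at least 977-fold higher. Csn1s1 had 4 counts against 10352 (-9.02, -11.07 to -7.84), Lalba 3 against 7810 (-8.98, -11.48 to -7.65) and Csn3 60 against 28431 (-6.73, -7.13 to -6.38).

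The alpha-globin gene Hba-a1 was at least 3140-fold higher in the late lung, with 2048 of its 2131 counts in 1 cell. The surfactant gene Sftpc was at least 859-fold higher, the endothelial gene Ramp2 at least 837-fold and Cd74 at least 641-fold. Lower in the lung were the potassium channel gene Kcnn4 (at least 90.7-fold), the collagen gene Col9a1 (-7.30), Trf (-6.09), the glycolytic gene Aldoc (-5.55) and Wfdc18 (469 against 67225 counts, -5.02, -5.15 to -4.89). Of the 469 late lung counts of Wfdc18, 346 lay in 1 cell. The median log2 ratio of all 1118 genes compared for scaling was 0.11. Summed without cells over 10000 UMIs, Kcnn4 was at least 20.8-fold lower, and Col9a1 stood at -5.11 and Trf at -4.37. The bounds for the genes higher in the lung were then 168-fold for Cldn5, 176-fold for Ramp2, 194-fold for Cd74, 663-fold for Sftpc and 2388-fold for Hba-a1.

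Milk and alveolar genes were lower in 11 of 14 members (median -5.28, and -5.06 at the bounds) and cell cycle genes in 24 of 29 (median -3.58, and -2.20 at the bounds), each below all random lists. Tyms was at least 10.5-fold, Cdk1 at least 9.88-fold and Mki67 at least 5.81-fold lower, and without cells over 10000 UMIs these bounds were 5.48-fold, 8.08-fold and 1.73-fold. Epithelial genes were lower in 13 and higher in 2 of 18 members (-2.32, and -1.44 at the bounds), with Epcam at -4.79 (-5.45 to -4.26), Cldn3 at -3.81, Krt7 at 4.51 and Krt19 at 8.87 (158 against 1 count). Without cells over 10000 UMIs the epithelial median was -0.95, Epcam -2.65 and Cldn3 -1.93. ERBB signalling genes were lower in 8 and higher in 1 of 13 members (-2.50, and -1.52 at the bounds, below all random lists). They included the ETS factor gene Etv5 (-4.01), the receptor gene Erbb3 (1 against 87 counts, -3.72, -9.62 to -1.78) and Erbb2 itself (3 against 87 counts, -2.50, -5.02 to -1.12), and Hbegf was higher (5.66). Without cells over 10000 UMIs the ratios of Erbb3 and Erbb2 were -1.38 and -1.48.

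Hypoxia and glycolysis genes were lower in 13 and higher in 3 of 19 members (-1.52, below all random lists), with the oxygen sensor gene Egln3 at -4.31, Pfkl at -3.27 and Vegfa at 3.76. Ndrg1 stood at 3.49 but at -0.15 without cells over 10000 UMIs. Extracellular matrix genes were higher in 12 and lower in 1 of 15 members (6.05, and 5.60 at the bounds), with Col4a1 at least 177-fold, and mesenchymal genes in 7 of 7 (6.63, and 5.67 at the bounds), with Sparc at 8.03 and Vim at 5.67. Cdh11 had 23 against 13 counts and was higher (2.94, 1.93 to 4.07). MHC class II genes were higher in 4 of 5 members (10.33, and 7.74 at the bounds), with H2-Ab1 at least 290-fold and H2-Aa at least 214-fold. Without cells over 10000 UMIs the bounds were 72.8-fold for H2-Ab1, 53.1-fold for H2-Aa and 61.2-fold for Col4a1. Dissociation stress genes were higher in 10 and lower in 1 of 18 (1.42, percentile 99.9), with the phosphatase gene Dusp1 at 6.07, Egr1 at 4.55 and Hspa1a at 2.79.

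In the dormancy list 7 members were higher, 4 lower and 5 neither (median 0.27, percentile 75.0, and -1.07 on the 6 members with at least 100 counts), with Cdkn1a at 4.67, Gas6 at 3.75, Col3a1 at least 48.6-fold higher and Igfbp5 at -5.43. Nr2f1 had 4 counts against 0, or 5.89-fold higher against the floor of 3 counts, which takes the 4 counts as exact. The pluripotency list had 3 members higher, 2 lower and 2 neither (1.06, percentile 93.5, and 4.54 on 5 members without cells over 10000 UMIs, 2.62 with every cell weighted the same and 6.48 on the 2 members with at least 100 counts), with Klf4 at 7.24, Klf2 at 5.72 and Myc at least 6.49-fold lower, and Zfp281 had 3 against 11 counts (0.43, -2.21 to 2.19). Basal and myoepithelial genes were higher in 4 of 4 members (7.23, and 5.93 at the bounds), with Acta2, a gene of smooth muscle too, at 6.05. Inflammation and NF-kB genes were higher in 3 and lower in 1 of 6 (1.28, percentile 98.9), with Icam1 at least 134-fold higher, Nfkbia at 2.16 and Lcn2 at -5.11. TGF-beta and BMP genes were higher in 7 and lower in 3 of 14 (1.43, percentile 99.7), with Id3 at least 354-fold higher. Without cells over 10000 UMIs the bounds were 99.4-fold for Id3, 91.3-fold for Icam1, 23.1-fold for Col3a1 and 3.17-fold for Myc. Nr2f1 then had 3 counts against 0, too few for a fold. Interferon genes were higher in 6 and lower in 5 of 16 (0.87), MHC class I genes higher in 4 of 11 (0.57), and Wnt genes higher in 3 and lower in 2 of 7 (0.10). Hormone-sensing genes were higher in 2 and lower in 1 of 3 (8.62, and 6.02 at the bounds). The higher ones were Ly6a and Cxcl15, the latter also a fixed alveolar type 2 marker. The lower one was Prlr (-2.53), which stood at 0.21 without cells over 10000 UMIs. Oxidative phosphorylation genes were lower in 5 of 23 (-0.61), and unfolded protein genes lower in 3 and higher in 1 of 16 (-0.27), with Xbp1 at -1.90.

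The comparison of late with early lung asks how lung cells differed between mice of the late stage and younger mice with no palpable tumor. In the late lung 5 of 5 measured MHC class II genes and 4 of 8 milk and alveolar genes were higher, the latter carried largely by a few cells. The globin gene Hbb-bs was higher, carried largely by 1 cell, and Dcn was lower. H2-Ab1 (chromosome 17, 34257689 to 34269419, plus strand), an MHC class II gene, had 197 counts against 10 (3.22, 2.37 to 4.37). Dcn (chromosome 10, 97479609 to 97518143, plus strand), the decorin gene of fibroblasts, had 0 counts against 134, at least 90.4-fold lower. Wfdc18 had 469 against 7 counts (4.95, 3.995 to 6.37), with 346 of them in 1 cell. The beta-globin gene Hbb-bs had 2561 against 25 counts (5.63, 5.10 to 6.29), with 2504 in 1 cell, and Mbp (5.66) had 243 of 255 counts in 1 cell.

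MHC class II genes were higher in 5 of 5 members (median 1.85, above all random lists), among them H2-DMb1 (3.55, 1.54 to 9.46), H2-Aa (1.55, 0.95 to 2.27) and the invariant chain gene Cd74 (1.40, 1.06 to 1.77). Without cells over 10000 UMIs the ratios of H2-Ab1, H2-Aa and Cd74 were 2.29, 0.74 and 0.74, and with every cell weighted the same 1.63, 0.35 and 0.22. Macrophage markers outside this list moved with it: endothelial-like cells up to 10000 UMIs held them at 4245 CPM in the late and 632 CPM in the early lung. In 1 cell each lay 215 of the 269 late UMIs and 34 of the 40 early UMIs. Of the MHC class I list 0 of 10 members passed 2-fold (0.39, percentile 98.5), with H2-K1 at 0.67 and H2-D1 at 0.41, the latter -0.02 without the deep cells. Dissociation stress genes were higher in 6 of 17 members and lower in none (0.81, above all random lists), including Hspa1a (2.04, and 1.11 without the deep cells), Socs3 (2.48) and Jund (1.20). Socs3 stood at -0.96 with every cell weighted the same. Unfolded protein genes were higher in 3 of 13 (0.53, percentile 98.8), among them Manf (1.08) and Creld2 (2.95).

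Milk and alveolar genes were higher in 4 of 8 measured members (1.33, above all random lists): Wfdc18, Csn3 (60 against 3 counts, 3.10), Lcn2 (2.81) and Trf (2.60). Of their late lung counts, 456 of 469, 52 of 60, 44 of 49 and 87 of 104 lay in the 5 luminal-like cells with 6 or more milk protein UMIs. Other genes lower in the late lung were Clec3b (-2.28, -2.80 to -1.80), Mfap4 (-1.99), Gpc3 (-2.56), Fbln1 (-3.90) and Serpinf1 (at least 12.8-fold). The share of fibroblast-like cells was 6.49% in the early and 2.86% in the late lung. The 6 late fibroblast-like cells held no UMI of Dcn, a leading gene of their cluster, so the share alone does not account for the Dcn ratio. The extracellular matrix list had 3 of 14 members lower (-0.10, percentile 24.5), and the basal and myoepithelial list 2 of 4 higher (0.83, percentile 97.7), led by Acta2 (2.89). TGF-beta and BMP genes were higher in 4 of 12 (0.51, percentile 96.5), with Smad7 (2.02), Smad6 (1.51) and Id1 (1.07), which were 0.54, 0.20 and 0.49 without the deep cells. Smad7 stood at -0.14 with every cell weighted the same.

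The mesenchymal list had 2 of 7 members higher (0.18, percentile 84.8): Cdh11, with 23 counts against 2 (2.22, 0.49 to 5.64, and 1.46 without the deep cells), and Zeb1 (1.73), which was -0.06 with every cell weighted the same. In the dormancy list Cdkn1a was higher (1.63, 1.19 to 2.11), and the other 10 members were neither (-0.07). In the pluripotency list Klf4 was higher (1.10, and 0.46 without the deep cells), and the other 2 members were neither (0.45). ERBB signalling genes were lower in 2 of 5 (-0.47), Spry2 at -1.55 and Phlda1 at -1.18. Hypoxia genes were higher in 1 of 14 (0.21; Ndrg1, 2.81), and 1 of 4 NF-kB genes was higher (0.28). No member passed 2-fold in the epithelial list (11 members, -0.30), the cell cycle list (3 members, 0.71), the interferon list (7 members, 0.24) or the oxidative phosphorylation list (23 members, -0.11). The same held for the hormone-sensing (0.29) and Wnt (0.30) lists, with 2 members each. The epithelial median turned to 0.41 with every cell weighted the same and to 0.25 without the deep cells. The 3 cell cycle members included Stmn1 (0.71, and -0.21 without the deep cells), a microtubule regulator gene also made outside dividing cells. Erbb2 had 3 counts in each lung library, Zfp281 3 and 0, and Nr2f1 4 against 6 (-1.55, -3.87 to 0.47). The median log2 ratio of all 642 genes compared for scaling was -0.15.

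The comparison of primary tumor with early lesion asks how the mammary site differed between the stages. Over all cells the milk and alveolar list had a lower median in the tumor. The ERBB signalling, interferon, and hypoxia and glycolysis lists had higher medians. In this order 9 of 18, 11 of 13, 8 of 14 and 7 of 18 members passed in that direction. Etv1 (chromosome 12, 38779380 to 38870484, plus strand), an ETS transcription factor gene, had 438 counts against 0, at least 302-fold higher, and Aqp5 (chromosome 15, 99590782 to 99594829, plus strand), a water channel gene, had 6320 against 90 (7.17, 6.88 to 7.50). Erbb2 had 87 against 28 counts and was 6.35-fold higher (4.16 to 10.2), or 2.67 on the log2 scale. Glycam1 (chromosome 15, 103562759 to 103565081, minus strand) had 3 counts against 18407 (-11.31, -13.81 to -9.99) and Csn2 117 against 199793 (-9.68, -9.96 to -9.43).

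Other genes far higher in the tumor were the collagen gene Col11a1 (8.80), Tesc (8.08), the cytokine receptor gene Il20rb (8.63), the Ras regulator gene Nf1 (6.86) and the neuropeptide gene Npy (at least 143-fold). Far lower were Spp1, the osteopontin gene (-9.46), the keratin genes Krt19 (1 against 3947 counts, -10.31) and Krt14 (at least 154-fold), the fatty acid carrier gene Fabp3 (at least 135-fold), Rspo1 (at least 127-fold) and Wap (-6.84). Without cells over 10000 UMIs Col11a1 stood at 6.48, Nf1 at 5.10 and Aqp5 at 5.93. Etv1 was then at least 139-fold and Npy at least 163-fold higher, and Krt14 was at least 69.3-fold, Fabp3 59.5-fold and Rspo1 58.7-fold lower. Erbb2 then stood at 1.17. The median log2 ratio of all 3933 genes compared for scaling was 0.24.

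In luminal-like cells alone (338 in the tumor, 1057 in the lesion) Npy was at least 183-fold and Etv1 at least 149-fold higher, Tesc stood at 8.41, the arginase gene Arg1 at 6.67 and Socs2 at 6.28. Glycam1 (-10.55), Spp1 (-10.88), Csn2 (-8.78) and Krt19 (-9.05) were lower, as were Wap (at least 104-fold) and Krt14 (at least 63.6-fold). The median of all 2002 genes compared for scaling was 0.43 there. Erbb2 had 9 against 27 counts in these cells (0.76, -0.57 to 1.84), so a difference in luminal-like cells was not detectable at this depth. Thinned to 1000 UMIs, Epcam was found in 557 of 1014 lesion (54.9%) and 59 of 261 tumor (22.6%) luminal-like cells, with 43 and 77 shallower cells left out.

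ERBB signalling genes were higher in 11 of 13 members over all cells (median 2.67, above all random lists) and in 4 of 10 in luminal-like cells (0.92, percentile 99.9), and lower in none. Etv5 (5.92, and 6.07 in luminal-like cells), Etv4 (5.91 and 6.94) and the ERK phosphatase gene Dusp6 (4.59 and 4.79) were higher in both sets, and the ligand gene Tgfa stood at 5.80 over all cells. Interferon genes were higher in 8 and lower in 2 of 14 members (2.03), and in luminal-like cells higher in 7 and lower in 1 of 12 (2.11), above all random lists in both. Examples were Oas1a (5.04), Ifi27l2a (4.69 and 5.96), Rtp4 (3.42 and 3.57) and Ifi27 (2.21 and 2.39). Hypoxia and glycolysis genes were higher in 7 of 18 members over all cells (0.73, percentile 99.8) and in 10 of 18 in luminal-like cells (1.17, above all random lists), and lower in 1 and 2. Car9, a carbonic anhydrase gene induced by hypoxia, was at least 31.7-fold and 42.4-fold higher, Egln3 stood at 3.90 and 4.31, Pfkp at 3.29 and 3.45, and Ndrg1 was lower (-3.84 and -3.35).

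Milk and alveolar genes were lower in 9 and higher in 4 of 18 members over all cells (-1.12) and lower in 11 and higher in 3 in luminal-like cells (-2.04), below all random lists in both. Lcn2, the lipocalin gene, was among those higher (2.41, 2.35 to 2.47). Dissociation stress genes were lower in 14 and higher in 1 of 20 members in each set (-2.08, and -2.42 in luminal-like cells, there -2.22 at the bounds), among them Fos (-3.65 and -5.16), Atf3 (-4.65) and Hspa1a (-4.71 in luminal-like cells). Inflammation and NF-kB genes were lower in 9 and higher in 2 of 11 (-2.41), and lower in 8 and higher in 1 of 11 in luminal-like cells (-2.31, and -1.87 at the bounds), with Nfkbia at -2.70 and -2.64 and the chemokine gene Ccl20 at least 21.9-fold and 9.26-fold lower. Cell cycle genes were lower in 10 and higher in 1 of 32 members (-0.80), and lower in 6 and higher in 1 in luminal-like cells (-0.41). Hmgb2 stood at -1.64 and -1.04 and Ccnb1 at -1.55 and -1.02, while Tk1 was higher in luminal-like cells (1.26). Basal and myoepithelial genes were lower in 7 of 9 (-5.39, and -2.79 at the bounds), and in 3 of 3 in luminal-like cells (-3.32, and -1.76 at the bounds). Extracellular matrix genes were lower in 7 and higher in 3 of 10 over all cells (-2.81, and -2.52 at the bounds), with Dcn at least 16.6-fold lower (8.07-fold without the deep cells) and Fbln2 at 5.14, and the 1 member measured in luminal-like cells stood at -1.41.

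Several lists stood apart between the sets of cells. The epithelial median was 0.15 over all cells, with 1 member higher and 4 lower of 20, and -1.29 in luminal-like cells, with 11 lower and none higher, among them Cldn4 (-2.85), Cldn3 (-1.84) and Cd24a (-1.83). Epcam stood at 0.94 (0.87 to 1.013) over all cells and at -0.40 without cells over 10000 UMIs. MHC class I genes stood at a median of -0.01 over all cells, with 1 of 11 lower, and at -1.85 in luminal-like cells, with 8 of 11 lower, among them Tap2 (-3.08), H2-Q4 (-2.38), H2-K1 (-2.29) and H2-D1 (-1.89). Unfolded protein genes were higher in 6 of 16 members over all cells (0.58, percentile 97.8) and higher in 4 and lower in 6 in luminal-like cells (-0.50, percentile 0.03). Herpud1 was higher in both (2.64 and 1.85), the chaperone genes Pdia4 (-2.69) and Calr (-2.11) were lower in luminal-like cells, and Hsp90b1 went from 1.65 to -0.39 without the deep cells. Within the tumor, luminal-like cells over cells over 10000 UMIs gave medians of -2.82 for MHC class I, -2.04 for epithelial and -1.30 for unfolded protein genes. Genes of membrane protein families stood at -1.44 and those of cytosolic families at 0.62 there. Dormancy genes were higher in 8 and lower in 4 of 15 over all cells (1.05, percentile 98.6), and higher in 3 and lower in 4 of 12 in luminal-like cells (-0.24, percentile 8.88). Cdkn1a (4.03 and 4.57) and Cdkn1c (3.44 and 4.58) were higher in both. The median over all cells was 0.24 without the deep cells and -0.02 with every cell weighted the same.

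MHC class II genes were lower in 3 and higher in 1 (H2-DMb1, 1.61) of 5 members (-4.51, and -1.89 at the bounds) and lower in 3 of 4 in luminal-like cells (-3.23, and -0.61 at the bounds), with Cd74 at least 11.8-fold and 4.90-fold lower. TGF-beta and BMP genes were higher in 6 and lower in 1 of 11 (1.03, percentile 95.4), with Ltbp2 at 5.75 and Tgfbr2 at 3.28, the latter 1.27 without the deep cells. In luminal-like cells that list had 2 higher and 1 lower of 7 (0.01). Wnt genes were higher in 4 and lower in 1 of 5 (1.54), with Wnt5b at -3.28, and 1 lower of 3 in luminal-like cells (0.33). Of the higher ones Znrf3 (1.90) stood at -0.11 without the deep cells. The pluripotency list had 2 members higher and 3 lower of 8 (-0.12, percentile 3.61), with Tfcp2l1 at 3.28 and Klf4 at -2.77, and 1 higher and 2 lower of 7 in luminal-like cells (-0.63). The mesenchymal list had 1 higher (Tcf4, 2.72) and 1 lower (Sparc, -2.57) of 4 (0.22) and 1 higher of 4 in luminal-like cells (-0.41). Hormone-sensing genes had 1 lower of 3 (0.80) and 2 lower of 2 in luminal-like cells (-2.79, and -1.49 at the bounds), and Prlr stood at 0.99 over all cells and -1.37 (-3.16 to -0.20) in luminal-like cells. No oxidative phosphorylation gene of 23 passed 2-fold in either set (0.10 and 0.43). Zfp281 had 11 against 20 counts (0.21, -1.02 to 1.32), Cdh11 13 against 20 (0.45, -0.70 to 1.51), and Nr2f1 had no counts in either mammary library.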

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

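The tests below were chosen after their results were seen, except the search for milk protein UMIs in shallow lung barcodes and the test of membrane against cytosolic gene families.

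The cell cycle list had a median log2 ratio of 0.71 for late over early lung and -0.80 for primary tumor over early lesion, but the lung value rests on 3 members inside the range of random lists (percentile 94.5) and the mammary value on 32, and the difference was not tested. The basal and myoepithelial list had 0.83 in the lung on 4 members and -5.39 in the mammary site on 9, and this difference was not tested either. Barcodes with at least 100 and under 500 UMIs, which no comparison uses, held over 50% mitochondrial UMIs in 69 cases in the early lung and 52 in the late lung (6.07% and 4.23% of such barcodes). They numbered 1147 in the early lesion and 2034 in the primary tumor (53.6% and 72.6%).

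Most called cells of the mammary libraries were poor in mitochondrial RNA, with medians of 0.119% in the early lesion and 0.463% in the tumor. Dilution by free RNA was argued against, since the free RNA itself held at least 23.4 times the median share of the called cells in both libraries. A low mitochondrial content of mammary cells as such stays open: lesion cells over 10000 UMIs, all 21 luminal-like, held a median 0.106% (quartiles 0.0936% and 0.137%), and such tumor cells held 4.63% (4.05% and 6.13%), but only 1 of those 18 was luminal-like. A joint loss of nuclear and mitochondrial RNA from damaged cells may contribute: cells under 1% mitochondrial RNA held 0.0395 (lesion) and 0.0334 (tumor) times the nuclear-retained RNA share of cells at 1% to 20%. Within luminal-like cells that ratio was 0.391 (0.329 to 0.466) in the lesion but 1.37 (0.747 to 2.78) in the tumor, on 11 nuclear UMIs, so the explanation stays open, as does a difference of tissue, which was not tested.

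Lung cell classes made up most cells of the lung libraries although the sort kept HER2+ cells. Free lung RNA as the source in all barcodes was argued against by the spread of alveolar type 1 and endothelial marker UMIs over barcodes. Their dispersion index was at least 11.0, where draws from 1 profile give 1. Free RNA alone in some barcodes stays possible, since some barcodes with such cells are enough to raise the index. The classes were also named with these same markers. Mammary-type cells rich in milk protein RNA, hidden under the UMI minimum, were argued against. At most 0.0880% of lung barcodes with at least 100 and under 500 UMIs held at least 3 milk protein UMIs at over 10 times the free RNA level. This rule cannot see mammary-type cells with little or no milk protein RNA, so it does not decide about them. Late lung luminal-like cells with 0.385% and 0.422% milk protein UMIs failed it even at 1557 and 3791 UMIs. Cancer cells with lung expression could not be excluded: 387 lung-class cells held 4 Erbb2 UMIs, against 27.8 expected at the level of all tumor cells and 6.90 at that of luminal-like tumor cells, and the counts do not separate the rat from the mouse gene.

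A few deep barcodes decided part of the tumor over lesion ratios, such as that of Epcam, which was 0.94 with the cells over 10000 UMIs and -0.40 without. Several luminal-like cells per barcode were argued against as their source, since the lower quartile of their mitochondrial share (4.05%) lay above the quartiles of luminal-like tumor cells (0.288% and 0.547%). A lower recovery of transcripts made at the endoplasmic reticulum in the shallow cells may contribute: genes of membrane protein families (236 genes) had a median log2 ratio of -1.44 in luminal-like over deep tumor cells and cytosolic families (139 genes) of 0.62, a difference of -2.06. An earlier form of this test on lists whose values were known, among them MHC class I (-2.82) and unfolded protein genes (-1.30), was replaced by it. A separate tumor cell state in the deep cells cannot be told apart from this, since there was 1 tumor library.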

How the results depend on the processing

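No paired analysis was made, and a model of site and stage over the 4 libraries together was not fitted. With 1 library per group no library could be left out. Of the values that answer a comparison (called cells, luminal-like shares, key list medians), 315 stayed within their limit under an alternative, 23 moved and 2 reversed. The limit was 1.5-fold for called cells, the 95% interval for shares, and for medians the 95% interval from the ranked members. For lists with under 6 members it was the full range of the members, which is not a 95% interval. For mesenchymal genes in tumor over lesion (4 members) it ran from -2.57 to 2.72, so staying within it says little. A list median counts as reversed where it changed sign and lay outside the 95% range of its random lists, and a gene where its interval excluded 1. In all 28 medians changed sign, of which 23 are among the 315 and 3 among the moved, with main values inside the range of random lists. They include the dormancy median for late lung over tumor, 0.27 and -1.07 with members of at least 100 counts. Some changed sign under median-of-ratios scaling, which shifts all genes alike and so does not move a list against other genes. These were dormancy for late over early lung, and epithelial and mesenchymal for tumor over lesion. For single genes, shares of cells and medians within endothelial-like lung cells, 4173 stayed, 382 moved and 27 reversed. A UMI minimum of 500, removal of the highest doublet scores (9 lesion cells and 1 tumor cell), Leiden resolution 0.5 and the 1-count minimum for list members moved none of these values past its limit, and subtraction of 5% free RNA moved 6 single genes. Some medians still changed sign within their limit. For tumor over lesion in luminal-like cells, the 1-count minimum gave 0.71 for mesenchymal (against -0.41), 0.34 for pluripotency (-0.63) and 0.10 for dormancy genes (-0.24). Over all cells it gave mesenchymal medians of -0.03 for late over early lung and -0.09 for tumor over lesion. Subtraction of 5% free RNA gave a luminal-like mesenchymal median of 1.58, on 2 members. No cluster was named immune-like, erythroid-like or platelet-like, so leaving such clusters out removed no cell. Its 20 values among the 315 and 352 among the 4173 could therefore not move. The minimum of 500 UMIs and the doublet removal left the lung cells unchanged. The late over early lung ratios over all called cells were therefore fixed there too. Thinning to 2000 UMIs moved 15 shares of cells with a UMI and no thinning moved 19.

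With 5 added counts, which pull genes at low counts toward 0, the early lung over lesion median was -0.92 for epithelial and -0.86 for cell cycle genes. For cell cycle genes it was -1.25 for late lung over tumor and 0.45 for late over early lung. At Leiden resolution 2.0 the luminal-like share of the lesion was 91.5%. With mitochondrial shares of at most 10% it was 98.5% in the lesion and 95.5% in the tumor.

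With a UMI minimum of 1000 the lung libraries held 55 and 79 cells, and the luminal-like shares were 14.5% (early lung), 24.1% (late lung), 98.8% (lesion) and 84.6% (tumor). A merged cluster with stromal leading genes took the luminal-like name there. For late over early lung the epithelial median was then -0.84 and Cox4i1 0.0107. Median-of-ratios scaling, which shifts all genes alike, gave cell cycle medians of 0.85 (late over early lung), -1.04 (tumor over lesion) and -0.85 (luminal-like cells). With members of at least 100 counts the pluripotency median for early lung over lesion was -0.15, against 1.10, and the dormancy median for late over early lung 0.69, on fewer genes.

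With every cell weighted the same, late over early lung gave 0.41 for epithelial and 0.54 for cell cycle genes, Krt7 0.40, Krt19 0.72, Zeb1 -0.0616, Stmn1 -0.198, Ly6a -0.0918, Smad7 -0.145, Ifitm3 -0.269, H2-D1 -0.252, Psmb9 -0.0758, Socs3 -0.96 and Jun -0.63. Tumor over lesion gave -0.0170 for dormancy genes, against 1.05, Prlr -0.59 and Sfrp1 -0.11.

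The sums without cells over 10000 UMIs were chosen after seeing the data. Late lung over tumor then gave an epithelial median of -0.95, Prlr 0.21 and Ndrg1 -0.15. Late over early lung gave 0.25 for epithelial and 0.57 for cell cycle genes, Krt7 0.0349, Krt19 0.17, Stmn1 -0.21, Ifitm3 -0.15, H2-D1 -0.0234 and Jun -0.12. Tumor over lesion gave Epcam -0.40, Prlr -0.92, Znrf3 -0.11, H2-T23 -0.0526 and Hsp90b1 -0.39. Both kinds of sum give deep cells less weight, and the cause beyond that was not tested. The lung values rested on 185 and 210 cells at medians of 772 and 811 UMIs.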

Other observations

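The lung comparison was also made within the 2 largest lung classes, a choice made after the data were seen, as were the values there without cells over 10000 UMIs. In endothelial-like cells (59 late, 76 early) MHC class II genes had a median log2 ratio of 1.24 for late over early (percentile 99.8 among matched random lists), and 1.19 on 3 members without the deep cells. H2-Ab1 had 188 counts against 9 (2.81, 1.93 to 4.03), or 888 against 120.5 CPM, and 56 against 9 (2.57, 1.61 to 3.84) without them. Macrophage markers outside the MHC class II list moved with the class: endothelial-like cells up to 10000 UMIs held them at 4245 CPM (3752 to 4783) in the late and 632 CPM (451 to 861) in the early lung. Of the 40 early UMIs, 34 also lay in 1 cell. Of the 269 late UMIs, 215 lay in 1 cell, which held 84 Lyz2, 65 Retnla and 30 Cd209f UMIs, no Cldn5 UMI and 14 of the 56 H2-Ab1 counts. Without that late cell too, H2-Ab1 stood at 2.31 (1.31 to 3.59) and the MHC class II list at 1.13. This was a choice made after the data were seen, and the early cell was kept. Extracellular matrix genes stood at 1.13 (percentile 99.1), dissociation stress genes at 0.73 (99.99) and unfolded protein genes at 0.73 (98.6), and without the deep cells at 0.95 (96.8), 0.35 (97.3) and 0.34 (94.4). Fibroblast markers moved with this class: they stood at 2237 CPM (2003 to 2491) in the 6 late endothelial-like cells over 10000 UMIs and at 63.1 CPM (17.2 to 162) in the other 53, while endothelial markers stood at 18605 and 14627 CPM. Gsn (2.48) and the fibroblast marker Tcf21 (3.54) were higher over all these cells, but without the deep ones Gsn stood at 0.45 (-1.39 to 2.48) and Tcf21 had 0 counts against 1. Lower in the late cells were Pir (2 against 12 counts, -3.83, -7.29 to -1.92) and Emc2 (6 against 17, -2.93, -4.64 to -1.60). The late endothelial-like cells included deep cells and held 51.4% of all UMIs of the late lung cells.

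In alveolar type 1-like cells (92 late, 61 early) no list with at least 3 measured members lay outside the 95% range of random lists. These lists were epithelial, extracellular matrix, MHC class I, hypoxia and glycolysis, oxidative phosphorylation, dissociation stress and unfolded protein. The other lists, MHC class II among them, had too few measured members in these cells, so a change there was not measured. The dissociation stress list stood at -0.33 (percentile 6.54), the oxidative phosphorylation list at -0.01 (68.5) and the epithelial list at -0.07 (42.8). Rgcc had 190 counts against 53 (1.46, 1.02 to 1.93), and Malat1 (1.76), Nme1 (3.08) and the Notch target gene Hes1 (2.43) were higher in the late cells. Bend7 (4 against 22 counts, -2.70, -4.83 to -1.28) and Dcun1d5 (2 against 17, -3.18, -6.62 to -1.39) were lower, and H1f0 had 0 counts against 11.

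Milk protein UMIs in the near-empty barcodes of the lung libraries were concentrated in barcodes that were called cells in the early lesion. In the early lung 305 of 531 such UMIs (57.4%) lay in these barcodes, which held 1.06% of the UMIs of the near-empty barcodes. In the late lung it was 200 of 408 (49.0%), against 0.569% of UMIs. No barcode was a called cell in more than 1 library. Milk protein genes made up 0.227% of the free RNA in the early lung and 0.128% in the late lung, and without the shared barcodes 1 of 1132 and 1 of 1226 barcodes with at least 100 and under 500 UMIs held at least 3 milk protein UMIs.

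The 5 late lung cells in luminal-like clusters that held 6 or more milk protein UMIs had mitochondrial shares between 0.128% and 0.234%. The median was 2.71% over all late lung cells and 0.463% in the tumor, where the lower quartile was 0.3125%, above these 5 cells. It was 0.119% in the early lesion, with quartiles of 0.0791% and 0.192%.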
